A study of Homo sapiens with 12 samples.

How the data were processed

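Total RNA of TK6 cells, a human lymphoblastoid line of B-cell origin used in genotoxicity testing, was isolated with an RNeasy Mini kit, enriched for polyadenylated RNA with a KAPA mRNA capture kit and sequenced in paired reads of 150 nt on a DNBSEQ-G400RS, per the labels' protocols. The submitters' processing notes name fastp 0.23.4, HISAT2 2.2.1, featureCounts 2.0.6, MultiQC 1.27 and the genome build GRCh38.p14. Their options, the use of strand and the treatment of reads with several alignments are not given in the sources used here.

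The authors deposited a table of raw read counts per gene for the 12 libraries, with 50006 rows that carry RefSeq names, coordinates and exon lengths. For each library they also deposited CPM, the count scaled to a library total of 1000000, which equalled that quotient within 5e-05 CPM and so carries no correction for composition. In each CPM file 51 gene names differed from those of the count table, with digits of the symbol rewritten as in a currency format. All other names stood in the same order, and names were taken from the count table. Of the names in that table, 43620 were also symbols in the reference annotation.

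Small counts were mostly even numbers. Over all genes and libraries 22533 values equalled 2 and 8873 equalled 1, and 68.7% of the values from 1 to 10 were even. Counting both reads of a pair separately leaves such a pattern, but its cause was not tested; if it is the cause, counts overstate the number of independent fragments. The floors cover counting error only. The table also lists genes of alternate loci and patch contigs as separate entries: 5953 names carry a copy suffix, as in GGNBP2_1, and those held 0.359% to 0.469% of a library's counts. Of the genes tested, 805 (6.69%) had such a copy entry or lay on such a contig, and they are called genes with a copy below. Reads that align equally well to both copies cannot be assigned to one of them, so the level of such a gene is uncertain, and the same holds for near-identical families such as histone genes.

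Library totals ran from 9163368 to 19841387 counts, with a median of 10097837. The floor used for undetected genes is 3 counts per library. Libraries of the same group differed by far more than sampling noise in a chi-square test over genes (8.25 to 155 per degree of freedom), and none was a duplicate of another. Samples were grouped by the concentration in their titles. The replicate numbers recur in each group, but the labels do not tie a number to a shared culture or day. The main fits, fixed in advance, did not use the numbers as a block. The deviations of same-numbered libraries from their group means had correlations from -0.38 to 0.58, so a shared effect of some numbers is not excluded.

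The groups, tests, gene lists, naming rule and all alternatives not described as added were fixed before the data were examined. Genes were kept with edgeR's filterByExpr on group (12030 genes), scaled with TMM factors and fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), all 12 libraries in 1 model with 8 residual degrees of freedom. Contrasts were each concentration against control, high against medium and medium against low. An F test asked whether any group differed, and a slope on the rank of concentration (0 to 3) tested a trend. Calls were made at a Benjamini-Hochberg adjusted p below 0.05. Standard errors of log2 fold changes came from the fitted weights and the posterior quasi-dispersion, and were checked against those implied by the F statistic (median ratio 1.00). The 29 fixed gene lists, of which 26 had at least 5 tested genes, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry.

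The text names for each concentration 7 fixed genes (CYP1A1, CYP1B1, AHRR, TIPARP, NQO1, CDKN1A and MDM2), up to 10 called genes per direction, up to 4 members of each list with a called test or called members, and, where no gene was called, the 5 genes with the smallest p as not passing; 1 of those in high is not reported. For the contrasts between treated groups and the trend it names 5 called genes per direction. Genes named outside the rule are marked as chosen after their values were seen.

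Alternatives covered DESeq2 size factors within edgeR, no composition factor, 2 other count filters, DESeq2 1.42.0, limma voom, limma-trend on log2 of the deposited CPM plus 1 or 0.1, a replicate block, a fold-change minimum, only the libraries of the groups compared, and each library left out in turn. DESeq2 was run on all 50006 rows, with its own filtering in place of filterByExpr. Its counts of called genes thus differ from edgeR's in gene set as well as in tool. Added after seeing the data were fits without genes with a copy, fits with 1 surrogate variable (sva 3.50.0) as a covariate, both together, this covariate with camera's estimated correlation, and fits without the 2 libraries highest in 7SL, 7SK and RMRP RNA. The surrogate variable was estimated from the tested genes, lists included, and correlated with their first principal component at r = 0.999. Fits with it are therefore no independent check of lists that lie along this component. Relations across the 12 libraries were tested with 100000 permutations, 2-sided. Single values compared between groups of 3 used the exact permutation test, whose smallest possible p is 0.1.

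The procedure was tested on simulated counts drawn from the real means, dispersions and library sizes. Over 3 simulations of high against control on 12030 genes, edgeR called 83.3% of genes changed 4-fold, 54.7% of those changed 2-fold, 17.9% of those changed 1.5-fold and 0.0394% of unchanged genes. On the same counts, changed in high alone, the slope on rank called 14.1%, 2.49% and 0.995% of these changed genes. DESeq2 called 0.245% of the unchanged genes in high against control, 87 over the 3 simulations. In low against control, where no gene was changed, DESeq2 called 11 over the 3 simulations and edgeR 0. DESeq2 was given only these 12030 genes here, unlike in the real fits, so its error rate there was not measured. Camera called a p53 list of 39 genes raised 1.5-fold in high and none of the other 25 lists. The simulated genes varied independently of each other, so this does not show how often camera calls lists of correlated genes in error.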

Results

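The transcriptome of TK6 lymphoblastoid cells was measured by RNA-seq after incubation with 3-methylcholanthrene, a polycyclic aromatic hydrocarbon carcinogen and a classical ligand of the aryl hydrocarbon receptor (AHR), for 24 h. There were 4 groups of 3 libraries each: control (0 µg/mL), low (0.0004 µg/mL), medium (0.04 µg/mL) and high (4 µg/mL). Library totals averaged 10865078 ± 2412124 counts in control, 9529316 ± 324354 in low, 10884886 ± 2078877 in medium and 15373063 ± 4194310 in high (SD, n = 3). Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No gene was called by edgeR's quasi-likelihood test in any comparison, while camera called lists of mitochondrial, histone and ribosomal protein genes. With an estimated correlation between genes 0 lists were called in low, medium or high (smallest adjusted p = 0.809, 0.966 and 0.470), and fry called 0 as well.

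The first question was whether the compound induced the AHR battery, here a list of genes that AHR switches on, only some of them detoxification genes. AHR itself (chromosome 7, 17298652 to 17346147, GRCh38.p14) had 0 counts in all 12 libraries, where the floor of 3 counts per library stands for 0.151 to 0.327 CPM if its reads were counted. CYP1B1 (chromosome 2), a hydrocarbon-metabolising cytochrome P450, and AHRR (chromosome 5), the AHR repressor, also had 0 counts throughout. So had FTH1, a ferritin gene of nearly all cells, whose exons are covered in full by other genes of the table, so a 0 in this table is not read as absence of expression. CYB5A and BACH2 had 0 counts too, with 0% of their exon bases covered by other genes, so such overlap does not account for all of these zeros. Other genes cover 97.2% of the exon bases of AHRR, 4.18% of AHR and 0% of CYP1B1 and CYP1A1, and whether AHR and CYP1B1 were not expressed or lost in counting was not settled. CYP1A1 (chromosome 15), a cytochrome P450 gene and classical AHR target, had 20 counts over all libraries and at most 4 in any one: 4 counts in control, 4 in low, 6 in medium and 6 in high. CYP1A2 had 7 counts in total. No induction of CYP1A1 was detected in these counts, and no fold is given for any of these genes. ARNT, the dimer partner of AHR, was chosen after its values were seen and stood at 35.8 ± 4.66 CPM in control and 31.1 ± 9.36 CPM in high (SD, n = 3).

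The battery genes with enough counts to test did not pass in any group. TIPARP (chromosome 3), an AHR-induced ADP-ribosyltransferase, stood at 35.6 ± 5.08 CPM in control and at 34.2 ± 4.17, 30.9 ± 1.37 and 33.9 ± 3.13 CPM in low, medium and high (SD, n = 3 each). Its log2 difference from control in high was -0.07, with a 95% interval from -0.35 to 0.22 (edgeR adjusted p = 0.873), and in medium -0.20 (adjusted p = 0.998). NQO1 (chromosome 16), a quinone reductase, differed from control by -0.17 ± 0.23 in low, -0.17 ± 0.23 in medium and -0.20 ± 0.23 in high (log2, SE; adjusted p = 0.912, 0.998 and 0.811). Of the 20 listed battery genes 5 were tested, namely TIPARP, NQO1, MYC, SLC7A5 and NFE2L2. The list median was -0.13 in low, -0.17 in medium and -0.20 in high (camera adjusted p = 0.632, 0.751 and 0.175). CYP1A1, CYP1A2, CYP1B1 and AHRR are not in it, so this median does not speak for them. No member was called over all genes or adjusted over the list alone. With 1 surrogate variable as a covariate, added after seeing the data, TIPARP and NQO1 in high turned to 0.0348 and 0.0493, and without control replicate 2 TIPARP in high turned to 0.0440, none of them called. With that covariate NQO1 also turned to 0.0320 in low and 0.00481 in medium, not called. With 1 library left out NQO1 ran from -0.36 to 0.0275 in low, -0.24 to -0.0633 in medium and -0.48 to -0.0545 in high, and TIPARP in medium from -0.30 to -0.0923.

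**Figure D1:**
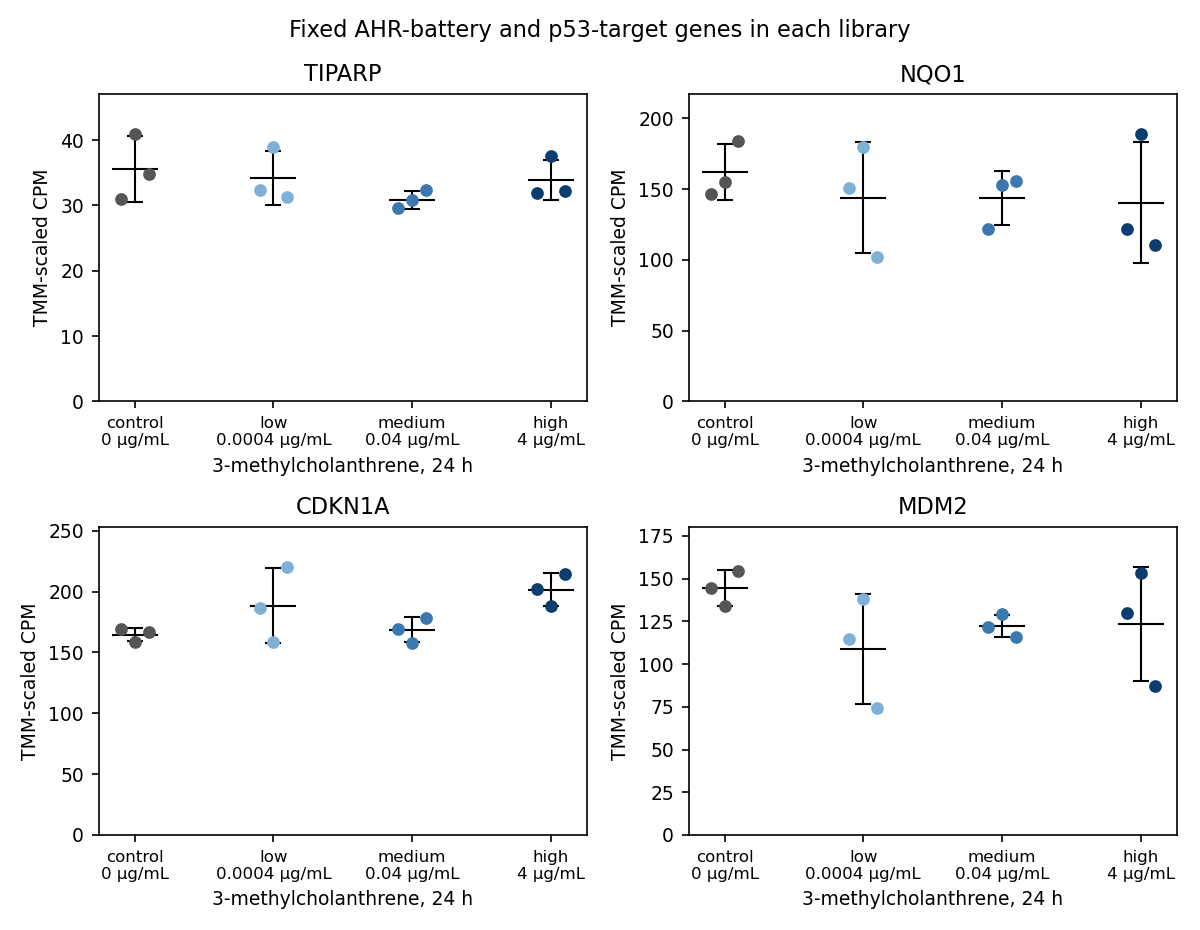
TMM-scaled CPM of TIPARP, NQO1, CDKN1A and MDM2 in each of the 12 libraries by concentration; points are libraries, the bar is the mean and the whiskers 1 SD (n = 3). CDKN1A in the 3 high libraries lies between 188 and 215 CPM, above the control range of 158 to 169 CPM, and TIPARP and NQO1 overlap between all groups.

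At 4 µg/mL the 13 protein-coding genes of the mitochondrial genome were all above control, with a median log2 difference of 0.37, and camera called the list up (adjusted p = 1.03e-08), a call lost with an estimated correlation (adjusted p = 0.470) and with fry (adjusted p = 0.202). CYTB, a subunit of respiratory complex III, measured 7224 ± 1417 CPM in control and 9443 ± 1000 CPM in high, and 3 complex I genes also lay higher: ND1 at 8016 ± 2499 and 11470 ± 1213, ND5 at 7226 ± 730 and 10449 ± 1644 and ND6 at 785 ± 270 and 1248 ± 55.5 CPM (SD, n = 3). Their log2 fold changes were 0.39 ± 0.14, 0.52 ± 0.19, 0.53 ± 0.20 and 0.67 ± 0.24 (SE; ND1 from 0.36 to 0.80 with 1 library left out), none of which passed over all genes (edgeR adjusted p = 0.810 each) or adjusted over the list alone (0 of 13, smallest 0.0662). All mitochondrial genes together took 15.7 ± 1.14% of counts in control and 20.5 ± 2.39% in high, with no overlap (exact permutation p = 0.1, 2-sided, the smallest that 3 against 3 allow). Within this share the 16S ribosomal RNA, whose link to RNA quality was not tested, took 2.48 ± 1.23% in control and 4.97 ± 3.29% in high, and the 13 coding genes alone took 12.9 ± 2.07% and 14.9 ± 1.68%, both overlapping (exact permutation p = 0.3 each). Leaving out high replicate 2, the median was 0.22 and the list was still called (adjusted p = 0.0344).

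Replication-dependent histone genes, whose transcripts end without a poly(A) tail, were called up as a list in high (camera, 18 of 21 tested members above control, median log2 0.78, adjusted p = 0.00255), a call lost with an estimated correlation (adjusted p = 0.470). H1-4 measured 0.802 ± 0.376 CPM in control and 2.61 ± 1.19 CPM in high (log2 1.71 ± 0.69, SE). Control libraries held few counts of these genes: 5 to 10 of H1-4, 4 to 19 of H2AC20, 8 to 22 of H1-5 and 19 to 39 of H2BC4. The log2 fold changes of H2AC20, H2BC4 and H1-5 were 0.90 ± 0.45, 0.73 ± 0.39 and 1.39 ± 0.77, and no member passed alone (adjusted p = 0.810 each). With 1 library left out H2AC20 ran from 0.51 to 1.20 and H1-5 from 1.07 to 2.10. Cytosolic ribosomal protein genes were called down (31 of 37 below control, median -0.15, adjusted p = 0.0121), also lost with an estimated correlation (adjusted p = 0.713). Of the members with the smallest p, RPS2 differed by -1.03 ± 0.60, RPL8 by -0.33 ± 0.23, RPL15 by -0.18 ± 0.17 and RPL23 by 0.13 ± 0.11, and none passed; with 1 library left out RPL8 ran from -0.65 to -0.17, RPL15 from -0.36 to -0.0749 and RPL23 from 0.0802 to 0.15. RPS2 was at 26.3 CPM in control replicate 3 against 5.27 and 6.04 CPM in the other controls, and turned to 0.13 without that library. RPS2 has a copy, and histone genes are near-identical to each other, so these levels are uncertain. In the same libraries 7SK RNA, which is not polyadenylated, averaged 13.4 ± 5.83 CPM in control and 43.6 ± 33.5 CPM in high, and 5.02 CPM in the lowest high library. Both list calls ended without high replicate 3 (adjusted p = 0.151 and 0.417, medians 0.47 and -0.0134) and without high replicate 1 (adjusted p = 0.0683 and 0.315, medians 0.65 and -0.0353). The ribosomal call ended without control replicate 2 or control replicate 3 as well (adjusted p = 0.0983 and 0.277, medians -0.11 and -0.0631), while its median was -0.27 without control replicate 1 and -0.38 without high replicate 2. With the surrogate variable the histone median was -0.0389, not called (adjusted p = 0.875), and the ribosomal list turned up, with a median of 0.0826 (adjusted p = 4.02e-08, or 0.343 with an estimated correlation). That covariate was estimated from genes that include both lists, so these changes are no independent check.

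Genes of the p53 pathway, the response to DNA damage, did not pass in high. CDKN1A (chromosome 6), the p21 inhibitor of the cell cycle, measured 165 ± 5.63 CPM in control and 202 ± 13.3 CPM in high (SD, n = 3), a fold of 1.22 with a 95% interval from 1.03 to 1.46 (edgeR adjusted p = 0.810). All 3 high libraries lay above all controls, where chance gives 10% of genes without overlap in either direction. MDM2 (chromosome 12), which degrades p53, lay on the other side at -0.23 ± 0.22 (log2, SE; adjusted p = 0.810), but at -0.0263 without high replicate 3 and -0.41 without high replicate 2. Of 39 tested p53 targets, 21 lay above and 18 below control, with a median of 0.08 (camera adjusted p = 0.169), and 0 were called over all genes or adjusted over the list alone.

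The other lists were not called in high. Camera's adjusted p was 0.0565 for NF-kB targets (12 of 15 above control, median 0.17), 0.135 for heat shock genes (median 0.12) and 0.135 for G2/M genes (median 0.06). Hypoxia and glycolysis genes had a median of -0.18 (0.106), NRF2 targets -0.21 (0.169), cholesterol synthesis genes -0.10 (0.180), lipid efflux and fatty acid genes -0.13 (0.151) and ER chaperones -0.12 (0.151). The medians of G1/S and replication (-0.05), nucleotide excision repair (-0.07), recombination and crosslink repair (-0.04), translesion synthesis (0.06), ATF4 targets (0.05), apoptosis regulators (0.02), AHR pathway components (-0.07), immediate early genes (-3.76e-04), interferon-stimulated genes (0.14), B cell identity (0.11), plasma cell genes (0.04), other xenobiotic metabolism (0.02) and stromal and epithelial markers (-0.11) came with adjusted p of 0.247 or more. Translesion synthesis, nucleotide excision repair and immediate early genes had means of the other sign (-0.0372, 0.0106 and 0.0555). Markers of T and NK cells, myeloid cells and erythroid cells had 2, 4 and 1 tested genes, too few for the test, with medians of -0.23, 0.39 and 0.35.

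Of 12030 genes tested between high and control, 0 passed (smallest edgeR adjusted p = 0.237), and 375 had an unadjusted p under 0.05 against 601.5 expected by chance. Voom called 1 of these genes, and DESeq2, run on all rows without this filter, called 5. Without control replicate 1 edgeR called 2. Among the smallest p-values, none passing, were those of GGNBP2_1 (log2 -3.10 ± 0.42), PIP4K2B_1 (2.59 ± 0.41), PSMC4 (-3.20 ± 0.57) and RPS29 (0.50 ± 0.10; SE). All of these but RPS29 have a copy, so their levels are uncertain. RPS29 (chromosome 14), a small-subunit ribosomal protein gene whose span holds the 7SL gene RN7SL1, measured 110 ± 6.12 CPM in control and 156 ± 16.3 CPM in high, and DESeq2 called it (adjusted p = 0.0451) where edgeR did not (0.810). RN7SL1 measured only 3.44 ± 2.16 CPM in control and 15.3 ± 12.2 CPM in high, and whether its reads enter the count of RPS29 was not tested. RPS29 also lay above all controls in 3 of 3 low and 3 of 3 medium libraries, at 131 ± 6.39 and 127 ± 9.73 CPM (SD). In simulated counts of the 12030 filtered genes DESeq2 called 11 genes over 3 simulations of low against control, where none was changed. The real DESeq2 fits took all rows, so this rate need not hold for them. DESeq2's few calls here and below have no measured error rate and are weak evidence. The median SE over genes was 0.20 on the log2 scale.

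**Figure D2:**
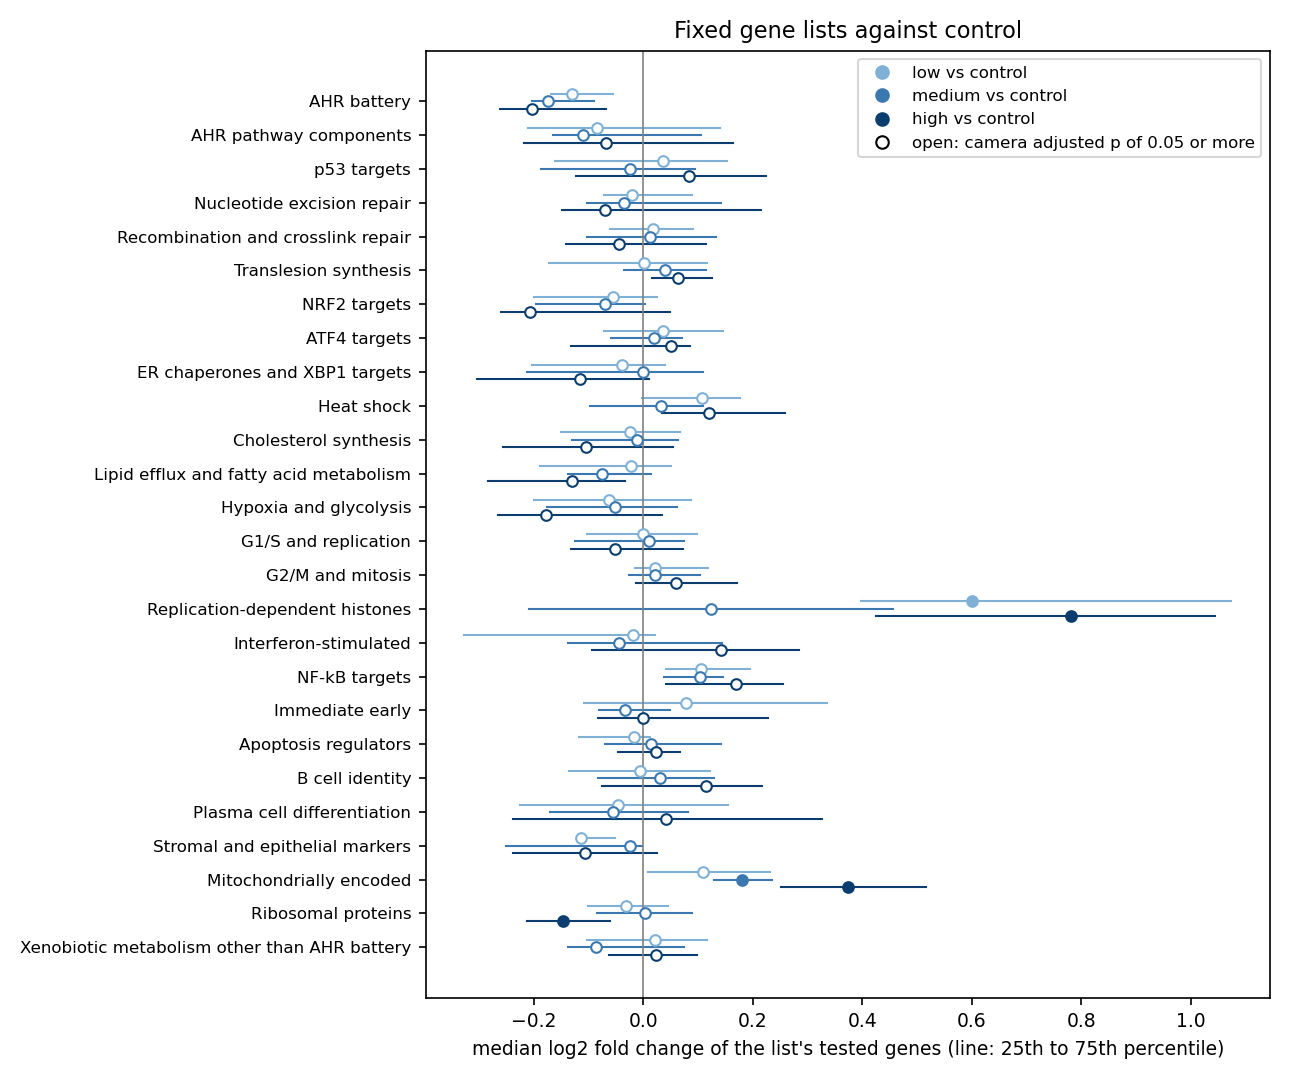
Median log2 fold change of each of the 26 tested gene lists against control, by concentration; lines span the 25th to 75th percentile of members, and filled points have a camera adjusted p under 0.05. Mitochondrially encoded genes have medians of 0.11, 0.18 and 0.37 in low, medium and high, and histone genes 0.60, 0.12 and 0.78.

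At 0.04 µg/mL camera called 1 list, the mitochondrially encoded genes, of which 11 of 13 lay above control (median log2 0.18, adjusted p = 0.00308; 0.966 with an estimated correlation). ND3 differed by 0.37 ± 0.17, COX1, the catalytic subunit of cytochrome c oxidase, by 0.19 ± 0.12, CYTB by 0.22 ± 0.14 and ND5 by 0.31 ± 0.20 (log2, SE), none passing (edgeR adjusted p = 0.998). With 1 library left out COX1 ran from 0.0992 to 0.28 and CYTB from 0.13 to 0.40. The mitochondrial share of counts was 18.0 ± 1.30% (control 15.7 ± 1.14%; exact permutation p = 0.2). CDKN1A at 169 ± 10.3 CPM and MDM2 at 122 ± 6.64 CPM differed from control by 0.03 ± 0.11 and -0.24 ± 0.22 (log2, SE; adjusted p = 0.998), and the p53 list had a median of -0.03 (adjusted p = 0.819). For MDM2 all 3 medium libraries (116 to 129 CPM) lay below all controls (134 to 155 CPM), where chance gives 10% of genes without overlap in either direction. Without control replicate 1, control replicate 2 or medium replicate 3 the mitochondrial call ended (adjusted p = 0.842, 0.472 and 0.300, medians 0.12, 0.0914 and 0.14), and without control replicate 3 the median was 0.34. The 16S ribosomal RNA took 3.55 ± 1.10% of counts in medium and 2.48 ± 1.23% in control.

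No gene was called between medium and control by edgeR (238 with an unadjusted p under 0.05), DESeq2 called 9, of which 8 have a copy, and voom called 1. Without control replicate 1 edgeR called 2. The 5 smallest p-values, none passing, were those of GGNBP2_1 (-3.04 ± 0.43), PSMC4 (-3.00 ± 0.57), EIF3CL (1.48 ± 0.30), GTF2H2C_2 (4.73 ± 1.05) and SLC37A4_1 (-1.01 ± 0.22; log2, SE). EIF3CL is a near-identical relative of the translation initiation factor gene EIF3C, and the others have copies, so all 5 levels are uncertain. EIF3CL measured 9.60 ± 0.504 CPM in control and 26.7 ± 5.06 CPM in medium (SD, n = 3; edgeR adjusted p = 0.998, DESeq2 adjusted p = 0.00654).

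At 0.0004 µg/mL camera called 1 list, the replication-dependent histones, with 19 of 21 members above control (median log2 0.60, adjusted p = 0.0115; 0.809 with an estimated correlation). H1-4 differed by 1.79 ± 0.70, H2BC9 by 0.79 ± 0.32, H1-5 by 1.53 ± 0.78 and H2AC12 by 1.42 ± 0.80 (log2, SE; edgeR adjusted p = 0.911 each). Except for H2BC9 (41 to 54) their control libraries held few counts: 5 to 10 of H1-4, 8 to 22 of H1-5 and 6 to 11 of H2AC12. Low replicate 1 held 2 counts of H2AC12, under the floor of 3. Without low replicate 3 the log2 fold changes of H1-4, H2BC9, H1-5 and H2AC12 were 0.77, 0.40, 0.62 and -0.25, the list's median turned to -0.11 and the call ended (adjusted p = 0.991), and without low replicate 2 the median was 0.96. With the surrogate variable it was -0.0276, not called (adjusted p = 0.884). Low replicate 3 was also the highest of the 12 in 7SL, 7SK and RMRP RNA, at 0.0141% of counts. CDKN1A at 188 ± 30.7 CPM differed by 0.19 ± 0.11 and MDM2 at 109 ± 32.3 CPM by -0.41 ± 0.22 (adjusted p = 0.911 each), from 0.0673 to 0.30 and from -0.62 to -0.20 with 1 library left out. TIPARP differed by -0.06 ± 0.13 (adjusted p = 0.935), and turned to 0.0555 without control replicate 2, 0.00405 without low replicate 3 and 0.0263 with the surrogate variable, not called in any of them. Mitochondrially encoded genes had a median of 0.11 and were not called (adjusted p = 0.399). The mitochondrial share of counts was 18.4 ± 3.87% in low (exact permutation p against control = 0.3), with 17.3%, 15.2% and 22.7% in replicates 1 to 3, and the difference from control of 2.71 percentage points was 0.558 without low replicate 3. The 16S ribosomal RNA took 4.28 ± 3.36% of counts in low and 7.99% in that library, and the 13 coding genes alone took 13.6 ± 0.0775%. Lists called numbered 2 without control replicate 1, control replicate 3 or low replicate 2, with ribosomal protein or mitochondrial genes added.

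Between low and control edgeR called 0 genes (339 with an unadjusted p under 0.05), DESeq2 called 4, all with a copy, and voom called 0. Without control replicate 1 edgeR called 2, and without low replicate 2 it called 1. GGNBP2_1 (-3.57 ± 0.46), PSMC4 (-3.91 ± 0.61), MGAT4B_1 (-4.47 ± 0.98), ZNHIT3_1 (-2.79 ± 0.60) and GTF2H2C_2_1 (2.16 ± 0.49; log2, SE) had the smallest p, and none passed (smallest adjusted p = 0.104). GGNBP2_1, on an alternate or patch contig, measured 10.5 ± 0.722 CPM in control and 0.873 ± 0.339, 1.29 ± 0.778 and 1.24 ± 0.531 CPM in low, medium and high. Its adjusted p was 0.104, 0.318 and 0.237 against the same control libraries, and the same gene's entry on the chromosome ranged from 1 to 170 counts over the 12 libraries.

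The direct contrasts between treated groups asked whether a step in concentration changed expression. High against medium gave 0 calls by edgeR (225 genes with an unadjusted p under 0.05), 4 by DESeq2, of which 3 have a copy, and 0 by voom. Medium against low gave 0 calls by edgeR (195 under 0.05), 6 by DESeq2, all with a copy, and 0 by voom, and 1 by edgeR without low replicate 2 or medium replicate 2. Over the 4 groups together the F test called 0 genes (210 with an unadjusted p under 0.05; smallest adjusted p = 0.0529, GGNBP2_1), against 21 by DESeq2, of which 20 have a copy, and 1 by voom. It called 4 without low replicate 2, 2 without control replicate 1 or high replicate 3 and 1 without medium replicate 1. The slope on the rank of concentration called 0 genes (348 under 0.05), against 1 by DESeq2, PIP4K2B_1, and 0 by voom. In simulated counts changed in high alone, the slope called 14.1% of genes changed 4-fold, so a change in high alone is mostly missed by it.

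**Figure D3:**
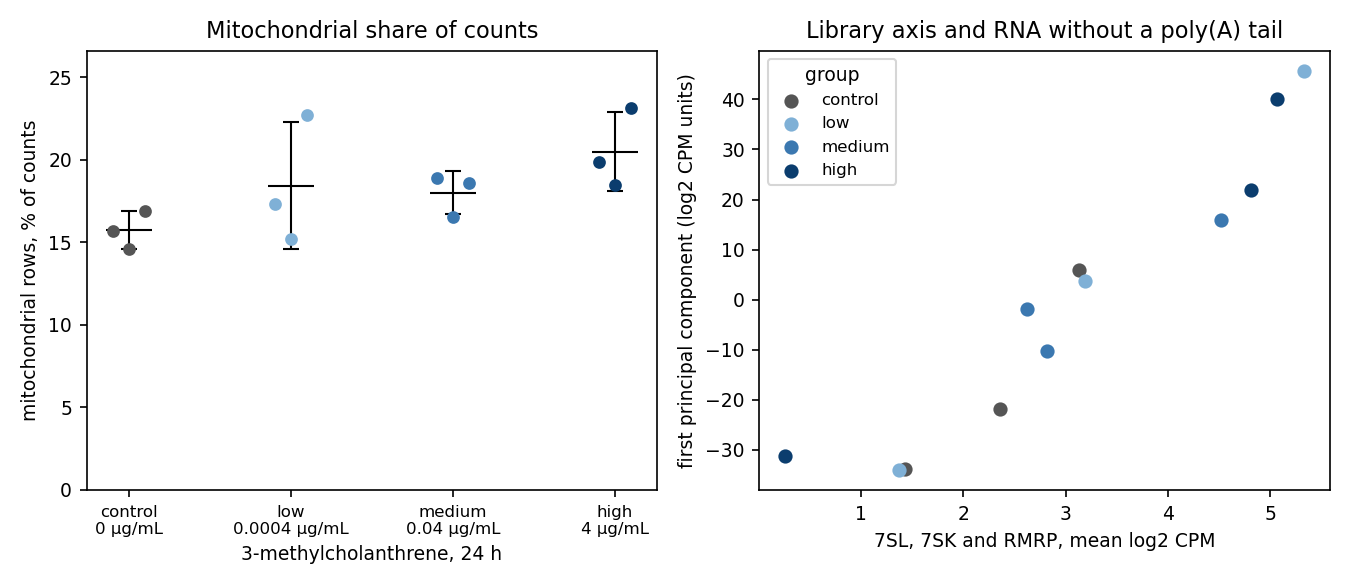
Left, share of counts in mitochondrial genes per library by concentration, with mean and SD (n = 3); the 3 high libraries lie between 18.5% and 23.1%, above the control range of 14.6% to 16.9%. Right, first principal component of log2 CPM, computed without those RNAs, against the mean log2 CPM of 7SL, 7SK and RMRP RNA in the 12 libraries; low libraries lie near both ends.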

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

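The fits with a surrogate variable, without genes with a copy and without the 2 libraries highest in 7SL, 7SK and RMRP were chosen after seeing the data. All 7 counts of 0 genes stayed at 0 with DESeq2 size factors in edgeR, CPM of at least 1 in 3 libraries, log2(CPM + 0.1) and without genes with a copy, and the 5 contrasts did so with a fold-change minimum. Counts are given in the order low, medium and high against control, high against medium, medium against low, F test and slope. Without a filter they were 3, 7, 4, 4, 3, 35 and 1, and with DESeq2, run on all rows, 4, 9, 5, 4, 6, 21 and 1. With log2(CPM + 1) the first 6 were 1, 2, 1, 1, 1 and 2. With voom, medium, high and the F test gave 1 each, and with no composition factor the F test gave 1. With only the libraries compared, low gave 1, medium 6 and high against medium 3. The slope on concentration itself gave 1. With a surrogate variable the counts were 1, 1, 2, 3, 1, 4 and 2; without genes with a copy as well, medium gave 1, high 3, high against medium 2, the F test 2 and the slope 2. Without the 2 libraries low, medium and high gave 1 each and the F test 2. With 1 library left out, counts ran from 0 to 2 for low, medium and high against control, 0 to 1 for medium against low and 0 to 4 for the F test, and stayed at 0 for the others. Without control replicate 1 each concentration gave 2. The replicate block gave 2 genes in the F test and changed no other gene count or list count. Same-numbered libraries had correlations of their deviations from -0.38 to 0.58, 8 of 18 over 0.1, and 6 of 12 libraries correlated best with their own number. Lists called were 0 at each concentration with an estimated correlation, with fry, and with a surrogate variable and an estimated correlation. With the surrogate variable alone, and without genes with a copy as well, low and medium gave 2 lists each, mitochondrial and ribosomal protein genes. Without the 2 libraries high gave 1. With 1 library left out, lists ran from 1 to 2 in low, 0 to 1 in medium and 1 to 4 in high. Ribosomal protein genes in high turned from a median of -0.15 to 0.0826 with the surrogate variable (adjusted p = 4.02e-08, or 0.343 with an estimated correlation) and to 0.0821 without genes with a copy as well. Histone genes in low ran from -0.11 to 0.96 with 1 library left out, turning without low replicate 3, and were at -0.11 without the 2 libraries (adjusted p = 0.991 and 0.989); with the surrogate variable their medians were -0.0276 in low and -0.0389 in high, not called (adjusted p = 0.884 and 0.875), although camera's direction stayed up. Mitochondrial genes in high stayed called in each fit with the preset correlation, with medians from 0.22 to 0.52. Of 910 values of the named genes under alternatives, 43 were called and 24, of 8 comparisons of a gene, changed sign, none of these called. With the surrogate variable, and without genes with a copy as well, TIPARP was at 0.0263 and 0.0244 in low and 0.0348 and 0.0329 in high, NQO1 at 0.0320 and 0.0274 in low, 0.00481 and 0.00373 in medium and 0.0493 and 0.0446 in high, and CDKN1A at -0.0334 and -0.0328 in medium. CDKN1A in medium was at -0.00251 with no composition factor, -0.00269 with log2(CPM + 1) and -0.00270 with log2(CPM + 0.1). Without the 2 libraries TIPARP and NQO1 in low were at 0.00453 and 0.0281. With 1 library left out, TIPARP ran from -0.16 to 0.0555 in low and -0.16 to 0.0440 in high, NQO1 from -0.36 to 0.0275 in low, H2AC12 from -0.25 to 1.96 in low, RPS2 from -1.39 to 0.13 in high and CDKN1A from -0.00671 to 0.0770 in medium. The cause of these changes was not tested, except that fewer libraries or more genes were in some fits by construction. CYP1A1, CYP1B1, AHRR and AHR lay at or near the floor in each library, and whether depth, absence or counting accounts for this was not tested, except that other genes cover 97.2% of the exon bases of AHRR.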

Other observations

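The tests of p53 targets with a covariate and all tests below, except that of S phase, that of other splits for genes with a copy and the counts of other splits, were chosen after the results were seen. With 1 surrogate variable as a covariate, camera called the p53 target list up in high (adjusted p = 0.00705, median log2 0.05), but not with an estimated correlation (0.115) or with fry (0.140). Without the covariate, FAS, a death receptor gene, differed by 0.28 ± 0.09, DDB2, a damage-recognition gene of nucleotide excision repair, by 0.28 ± 0.10 and CDKN1A by 0.29 ± 0.11 (log2, SE), while MDM2 lay at -0.23 ± 0.22. FAS and DDB2 were chosen after their values were seen, and none passed (edgeR adjusted p = 0.810 each). FAS was at 77.3 ± 3.73 CPM in control and 93.9 ± 8.82 CPM in high, above all controls in 3 of 3 libraries, where chance gives 10% of genes without overlap. DDB2 lay above control by 0.27 ± 0.10 in low and 0.33 ± 0.10 in medium as well, against the same control libraries and without passing (adjusted p = 0.911 and 0.998).

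Leaving out genes with a copy and adding the surrogate variable, edgeR called 3 genes in high: RPS29 (log2 0.50, adjusted p = 0.00708), ATP8 (0.95, 0.00708), a mitochondrial ATP synthase gene that overlaps ATP6, and the mitochondrial tRNA gene TRNP (0.41, 0.0381). ATP8 stood at 242, 520 and 228 CPM in high replicates 1 to 3 and at 156, 152 and 294 CPM in control, so only high replicate 2 lay above all controls. The same setting called EIF3CL in medium (1.40, adjusted p = 0.00316) and no gene in low.

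Other splits of the libraries were refitted. Each contrast of 3 against 3 has 10 splits, too few for a share under 0.05. The real splits called 0 genes and the highest other called 1 for low, medium and high against control and 0 for high against medium and medium against low, so 10 of 10 splits in each gave as many. For gene lists the real counts were 1 in low, 1 in medium and 3 in high, the highest others 3, 3 and 4, and 10, 7 and 2 of the 10 splits gave as many. For the F test and the slope, 100 of 100 drawn splits gave at least the real count of 0, which any split must, so this says nothing on chance. Of the 99 others, 93 in the F test and 95 for the slope called at most 2 genes, and the remaining 6 and 4 called up to 3437 and 5308, which points to a structure of the libraries other than concentration.

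The first principal component held 37.4% of the variance of all genes, and a median of 71.8% of its own variance lay between the groups in the 6 splits with most calls in the F test, against 17.6% in the other 93 (rho of this share with the genes called = 0.261, permutation p = 0.00879). The component is the widest spread of the same genes in the same 12 libraries. More calls in splits along it therefore follow largely from how it was built. The splits also reuse these libraries and are not independent, so no conclusion is drawn from this p-value. In the order control to high, libraries numbered 1 lay at 6.44, 4.21, 17.9 and 24.4 on the component. Those numbered 2 lay at -24.4, -37.9, -11.4 and -33.7, and those numbered 3 at -37.4, 51.1, -3.23 and 44.1. Numbers 1 and 2 thus lay apart on this axis, and whether replicate number accounts for part of it was not tested. A candidate explanation of this axis is uneven carry-over of RNA without a poly(A) tail: the component, computed without histone and small RNAs, correlated over the 12 libraries with the mean of the histone list (Pearson's r = 0.922, permutation p = 2e-05, adjusted 2.5e-05 over 5 relations; Spearman's rho = 0.860, p = 6e-04; r = 0.829 without low replicate 3 and high replicate 3). It also correlated with 7SL, 7SK and RMRP (r = 0.955, rho = 0.965), with the share of 16S ribosomal RNA (r = 0.979, rho = 0.979) and with that of ribosomal proteins (r = -0.949, rho = -0.979), each with a permutation p of 1e-05, the smallest possible (adjusted 1.67e-05), and r of 0.937, 0.983 and -0.895 without the same libraries. A response to the compound is argued against, since the 3 low libraries alone spanned the whole range (a share of 1). A different share of S-phase cells stays open: histone and G1/S genes had r = 0.485 (permutation p = 0.109), rho = 0.657 (p = 0.0240) and r = 0.305 without the same libraries. The sizes were unlike, however. Over the 12 libraries the G1/S mean ran only from 7.06 to 7.12 log2 CPM, while the histone mean ran from 0.490 to 2.23. A shared shift, if any, was thus far smaller in G1/S genes.

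Genes with a copy held most of the smallest p-values: 29 of 805 had p under 0.01 in the F test against 6 of 11225 others (odds ratio 69.9, Fisher's exact p = 5.96e-29). This count restates the pattern and does not test its cause. Reads shared between near-identical copies may give it, as they may give these genes' median biological coefficient of variation of 0.503 against 0.173. For high against control, a response to 3-methylcholanthrene as the source of such genes among the smallest p-values is argued against by other splits of those libraries. Their 100 smallest p-values held a median of 45.0 genes with a copy (5 to 68) against 34 in the real split. The excess in the F test was not compared with other splits.

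The mean log2 CPM of the mitochondrial list had a slope of 0.120 per step of concentration (95% interval of a linear model 0.0252 to 0.215; r = 0.665, permutation p = 0.0168; rho = 0.583, p = 0.0554), but r = 0.454 (p = 0.189) without control replicate 1 and high replicate 2, while the 9 treated libraries alone gave a slope of 0.135 and r = 0.728. Carry-over is argued against as its whole cause, since the slope was 0.134 (0.0381 to 0.229) with 7SL, 7SK and RMRP as a covariate. A shift of short against long transcripts stays open: 524 nuclear genes of the same lengths had a median of 0.0363 in high, but quartiles of -0.15 and 0.32 that overlap the mitochondrial lower quartile of 0.25. A response to the compound and chance both stay open, as do differences in cell density or RNA handling, which were not tested.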
